A study of Homo sapiens with 20 samples.

How the data were processed

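The samples were tissue of 5 healthy and 5 failing human hearts, and the part of the heart is not given in the sources used here. From each heart came an input library, which measures RNA abundance, and a library of RNA fragments pulled down with an antibody against N6-methyladenosine (m6A), called IP here, so that there were 20 libraries in 4 groups of 5. Per the labels, RNA was extracted with TRIzol, polyadenylated RNA was selected, ribosomal RNA was removed, and the RNA was sonicated. Part of it was kept as input, and the rest was immunoprecipitated with the EpiMark m6A kit before stranded TruSeq libraries were made.

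The deposited values of each library are raw counts per gene, with the 5 summary lines that HTSeq writes for reads given to no gene. The authors' notes name HISAT2 2.2.0, HTSeq 2.0 and DESeq2. The strand setting of the counting is not given in the sources used here. The authors' deposited table of failing against healthy input holds log2 fold changes with their standard errors from DESeq2, and its p-value columns hold Wald p-values and adjusted p-values, per the file headers. The authors' 3 peak lists, which carry the name of exomePeak, were deposited with a score that is a p-value, 1 list per condition and 1 for failing against healthy, so that the libraries of a condition were used together and a list has no replicates. The processing notes name the build hg19, whereas 97.0% to 97.5% of the peaks lay within the GRCh38 bounds of the gene they were named for, so GENCODE 29 on GRCh38 was used for all positions.

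The count tables held 60662 genes, of which 99.96% had a symbol. XIST, TSIX and genes on the Y chromosome (601 in all) were left out of every step, which left 60061. The input libraries held 9791865 to 17806383 gene counts (median 12129138 in healthy and 12873098 in failing hearts) and the IP libraries 16544962 to 23261520. Reads given to no gene, including those with several alignments, made up 53.6% to 68.8% of all reads of an input library and 29.6% to 39.6% of an IP library. An input library had counts for 23207 to 30379 genes and an IP library for 14825 to 26622. Counts were modelled with a spread between hearts, so errors cover differences between hearts as well as counting. No library was left out of the reported values. Results for 3 genes of the tables are not reported here, and these genes were left out of the search for values that lie apart, while the fits and gene lists include them.

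Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood fits and F tests), with limma 3.58.1 for gene lists and DESeq2 1.42.0 as an alternative. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. Expression in failing against healthy hearts used the 10 input libraries. IP against input in healthy hearts, IP against input in failing hearts, and the change of the IP-to-input ratio between conditions were contrasts of 1 model of all 20 libraries with 4 group means, in which the heart was a block only as an alternative. Log2 values per library used a prior count of 2. CPM stands for the usual normalised read count, scaled to the library's total after TMM, SE for the standard error of a fitted log2 value and SD for the standard deviation between hearts.

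In all, 29 gene lists with 582 genes were written before the data were examined, as were the comparisons, tests, alternatives and the rule for naming genes. They cover cardiomyocyte programs, matrix and growth factor signalling, metabolism, the m6A machinery, stress and immune responses, ribosomal and mitochondrially encoded genes, and markers of cell types. The lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry, adjusted over the lists. Counts of list members adjusted over the list alone are given beside those adjusted over all genes.

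Named genes were chosen by the fixed rule. For expression these were up to 8 genes each way past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, at most 2 members each way of each list that passed camera or holds cell-type markers, and all m6A machinery genes. For IP against input they were the 6 genes with the highest and the 6 with the lowest mean ratio among genes past the threshold in both conditions, and for the change of enrichment the 8 genes each way with the smallest p. For peaks the rule named the 5 genes with the smallest p, which could be applied to the differential list but not to the condition lists, where 2483 and 2850 peaks share a p of 0. Not named were HLA, immunoglobulin and T cell receptor genes and genes with common deletions. Genes chosen after their values were seen are marked as such where they appear.

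Peaks of both conditions counted as shared when they overlapped by at least 1 base of exon on the same strand. Peaks were placed on 1 coding transcript per gene, as 5′ UTR, coding sequence, within 200 bases of the stop codon, or 3′ UTR, beside random positions of the same transcripts. The consensus motif DRACH of m6A sites was counted in peaks and in stretches of equal length outside peaks of the same transcript. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and plots were drawn with matplotlib 3.10.9.

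On simulated counts of the same size and spread, with 100 genes changed by 1 and 100 by 2 on the log2 scale, the expression test recovered 34.0% and 91.0% of them with 5.30% false calls. IP against input in healthy hearts recovered 28.0% and 85.0% with 3.40% false calls, and the change of enrichment 2.0% and 48.0% with 5.70% false calls. With the heart as a block, on counts simulated with the levels of each heart and the spread of that fit, the change of enrichment recovered 34.0% and 80.0% with 5.0% false calls. All changed genes had a mean log2 CPM of at least 1. Without the block, the simulated input and IP library of a heart were drawn independently, whereas the real ones vary together (r 0.36 to 0.78). For IP against input and the change of enrichment, those shares are therefore not the power in these data.

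Whether the input and IP library with the same number came from the same heart was checked on deviations from the group mean across genes, which are not independent replicates. Pearson's r was 0.36 to 0.78 for libraries with the same number and −0.43 to 0.04 for others, and 10 of 10 input libraries matched best the IP library with their number. Healthy and failing hearts with the same number are different hearts (r −0.22 to 0.11). No pair of libraries of a group held duplicated counts (lowest chi-square per degree of freedom 19.0), and 0 of 10 hearts showed a mismatch between its input and IP library in a check for mixed-up samples. Alternatives were another scaling, another test, no filter on low counts, non-robust fits, blocks, each heart left out in turn, other list tests, and stricter peak overlaps and thresholds.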

Results

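Input and m6A-IP libraries of 5 healthy and 5 failing hearts were compared for RNA abundance, for the enrichment of transcripts in the IP and for the places of the m6A peaks. The question behind the comparisons was whether marks of m6A on heart transcripts differ with heart failure. All n are hearts, 5 per group.

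CHRDL1 and CD14 were the 2 genes whose abundance passed the test between failing and healthy hearts. CHRDL1 codes for a secreted antagonist of bone morphogenetic proteins and lies on chromosome X (110673856 to 110795819). It rose from 1.01 ± 0.39 to 5.84 ± 1.42 CPM (SD, n = 5), a log2 fold change of 2.52 ± 0.32 (SE, adjusted p = 0.0154). CD14 codes for a co-receptor of bacterial lipopolysaccharide on monocytes and macrophages and lies on chromosome 5 (140631728 to 140633701). It fell from 33.9 ± 8.10 to 9.29 ± 2.63 CPM, a log2 fold change of −1.87 ± 0.23 (adjusted p = 0.0154). For both genes every failing heart lay outside the range of the healthy hearts.

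Several members of the fixed lists had large fold changes without passing over all genes. NPPA, which codes for atrial natriuretic peptide, averaged 52.7 ± 61.2 CPM in healthy and 494 ± 282 in failing hearts (log2 3.22, SE 0.72, adjusted p = 0.113). PI16, a peptidase inhibitor made by fibroblasts, averaged 20.2 ± 14.4 and 103 ± 38.4 CPM (log2 2.34, SE 0.48, adjusted p = 0.0950). SOX17, a transcription factor of endothelial cells, averaged 7.97 ± 1.68 and 22.3 ± 9.36 CPM (log2 1.49, SE 0.28, adjusted p = 0.0721). GJA1, which codes for the gap junction protein connexin 43, averaged 113 ± 25.4 and 59.8 ± 6.70 CPM (log2 −0.92, SE 0.19, adjusted p = 0.0880).

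Of 14950 genes tested with edgeR, 1 passed as higher and 1 as lower at an adjusted p below 0.05, while 26 and 35 had an adjusted p below 0.1. An unadjusted p below 0.05 was reached by 2455 genes, where 748 would be expected by chance. DESeq2 in place of edgeR called 568 genes (218 higher, 350 lower), and edgeR without healthy heart 3 called 133. CD14 no longer passed without failing heart 2, 4 or 5 (log2 −1.76 to −2.05 over the 10 fits with a heart left out), and CHRDL1 without healthy heart 1 or failing heart 2, 4 or 5 (log2 2.36 to 2.75).

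**Figure D1:**
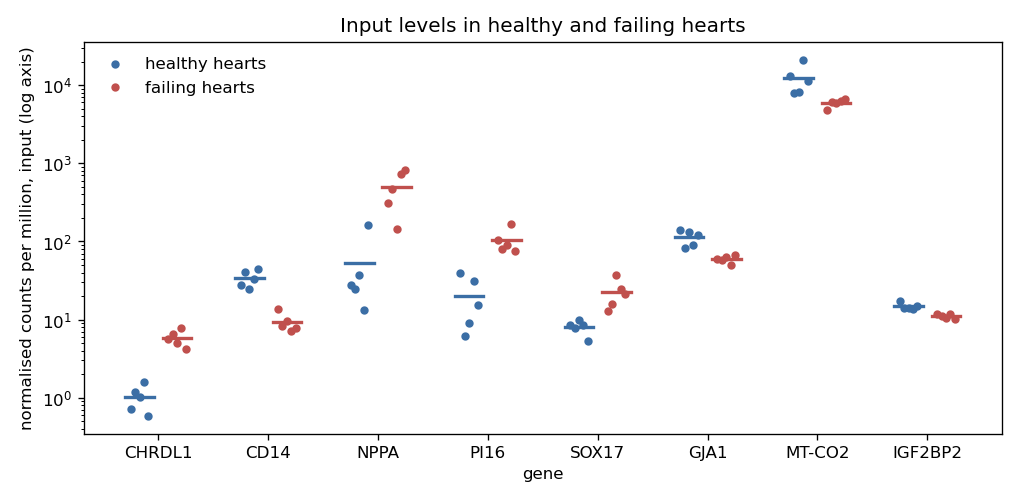
Normalised CPM of 8 genes in the input libraries of healthy and failing hearts on a log axis, with 1 point per heart and a bar at the group mean. CHRDL1 averaged 1.01 CPM in healthy and 5.84 in failing hearts, and CD14 averaged 33.9 and 9.29.

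Macrophage and monocyte markers fell as a list in failing hearts, with a median log2 fold change of −0.98 and 16 of 16 measured members below 0 (camera, adjusted p = 3.66e-11, or 0.554 with an estimated correlation). Besides CD14, the list holds FCER1G, the shared signalling chain of Fc receptors (log2 −1.45, SE 0.36), VSIG4, a complement receptor of resident macrophages (−1.41, SE 0.37), and C1QB, a chain of complement C1q (−1.19, SE 0.33). CD163, a scavenger receptor and the most abundant of the 16, averaged 137 ± 71.6 CPM in healthy and 75.03 ± 19.7 in failing hearts (−0.87, SE 0.34). CD163 and C1QB were chosen after their values were seen, and CD163 and VSIG4 are also in the acute phase list. Of the members 1 passed over all genes and 11 passed as lower when adjusted over the list alone.

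Mitochondrially encoded genes fell as a list, with a median of −0.73 and 11 of 13 members below 0 (adjusted p = 9.21e-07, or 0.554 with an estimated correlation), 10 of them lower when adjusted over the list alone and 0 over all genes. MT-CO2, a subunit of cytochrome c oxidase, averaged 12290 ± 5233 CPM in healthy and 5888 ± 695 in failing hearts (log2 −1.06, SE 0.28). MT-ND3, a subunit of complex I, had a log2 fold change of −1.19 (SE 0.31), while MT-ND5 and MT-ND6 stood at 0.07 (SE 0.27) and 0.12 (SE 0.26).

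Ribosomal protein genes fell with a median of −0.41 and 30 of 31 members below 0 (adjusted p = 4.60e-06, or 0.554 with an estimated correlation), among them RPL7 at −0.59 (SE 0.23), while RPL22 stood at 0.07 (SE 0.20). None of the 31 passed over all genes (edgeR) or when adjusted over the list alone, and 6 had an unadjusted p below 0.05. Reads outside genes made up 17.8% ± 2.72 (SD) of the uniquely aligned reads in failing and 13.3% ± 1.90 in healthy input libraries (exact two-sided permutation p = 0.00794, the smallest the design allows). Mitochondrially encoded genes took 16.8% ± 2.80 and 23.3% ± 5.34 of gene counts (exact two-sided permutation p = 0.0476). The share of reads outside genes moves with the condition as both lists do.

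Immediate early genes, which are switched on first by stimulation, rose as a list with a median of 0.72 and 22 of 23 members above 0 (adjusted p = 1.66e-05, or 0.554 with an estimated correlation). KLF4 stood at 0.69 (SE 0.19) and IER2 at 0.89 (SE 0.29), whereas FOSL1 stood at −1.95 (SE 1.20), and at 0.86 without healthy heart 2. None of the 23 passed over all genes or when adjusted over the list alone, by edgeR, and 7 had an unadjusted p below 0.05. Acute phase and cytokine genes fell with a median of −0.64 and 13 of 16 members below 0 (adjusted p = 0.00109, or 0.554 with an estimated correlation), with 7 members lower and 1 higher when adjusted over the list alone. VSIG4 and PLA2G2A, a secreted phospholipase (log2 −2.05, SE 0.58), were among the lower ones, and the chemokine gene CXCL2 was the higher one (log2 1.30, SE 0.47, and 0.72 without failing heart 1).

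The fetal and stress program of cardiomyocytes rose with a median of 0.41 and 14 of 18 members above 0 (adjusted p = 0.0259, or 0.554 with an estimated correlation). NPPA and MSS51, a muscle gene of mitochondrial metabolism (log2 1.49, SE 0.32), were the 2 members that passed when adjusted over the list alone. Among the lower members, ANKRD2 stood at −0.835 (SE 0.60) and XIRP2 at −0.87 (SE 0.64). For XIRP2, healthy heart 2 held 6403 CPM and the other healthy hearts 785 to 1612. The TGF-beta pathway (median 0.16, adjusted p = 0.0410, or 0.554 with an estimated correlation) included SMAD7, an inhibitor of the pathway, at 0.88 (SE 0.25) and BMP4 at 0.98 (SE 0.33), with 0 members past the threshold over the list alone (edgeR) and 5 with an unadjusted p below 0.05. Fibroblast markers (median 0.13, 12 of 18 above 0, adjusted p = 0.0469, or 0.554 with an estimated correlation) had PI16 as their 1 member that passed when adjusted over the list alone, while MEOX1 stood at −0.84 (SE 0.34) and COL1A1 at −1.21 (SE 0.93), and at −0.54 and 0.95 without healthy heart 2. Extracellular matrix genes were called upward by camera (adjusted p = 0.0259, or 0.703 with an estimated correlation). Their median was however 0.045 and their mean −0.015, a mean lowered by healthy heart 2 (COL1A1 at 1007 CPM and TNC at 209). Their 2 members that passed over the list alone, FRZB (log2 1.86, SE 0.38) and SFRP4 (1.98, SE 0.52), code for secreted Wnt antagonists, while TIMP1, an inhibitor of matrix proteases, stood at −1.20 (SE 0.45), and at −0.64 without healthy heart 2.

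None of these 9 lists passed with an estimated correlation between genes, and fry for change in 1 direction gave no list an adjusted p under 0.156. Fry for change in either direction gave these 9 lists adjusted p of 0.0127 to 0.139. The macrophage, mitochondrial, ribosomal, immediate early and acute phase lists passed camera at the preset correlation in 10 of 10 fits with a heart left out. The fetal list no longer passed without healthy heart 4 or 5 or failing heart 1 or 4 (adjusted p up to 0.145). The matrix list was lost without healthy heart 1, 3 or 4 or failing heart 4 (up to 0.367), the TGF-beta list without healthy heart 3 or 4 or failing heart 1 or 4 (up to 0.241), and the fibroblast list without healthy heart 3 or 4 or failing heart 2 or 4 (up to 0.241).

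**Figure D2:**
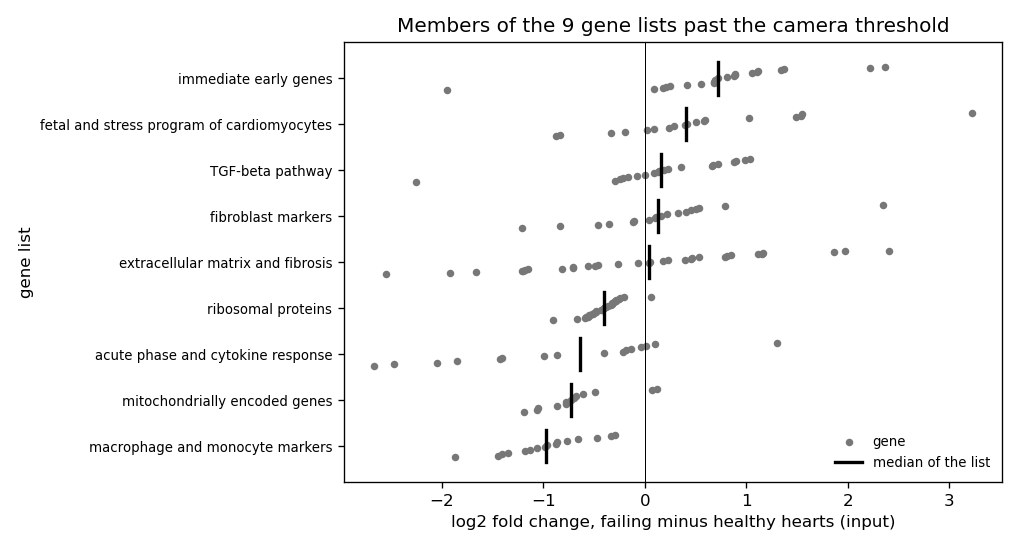
Log2 fold change (failing minus healthy) of each member of the 9 gene lists past the camera threshold, with 1 point per gene and a bar at the list's median. The medians ran from −0.98 for macrophage and monocyte markers to 0.72 for immediate early genes.

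The genes of the m6A machinery had small fold changes, with a median of 0.11, 12 of 20 above 0 and 0 past the threshold over all genes or over the list alone by edgeR (camera adjusted p = 0.467). METTL3, the catalytic subunit of the m6A writer, averaged 25.8 ± 7.34 CPM in healthy and 25.5 ± 3.44 in failing hearts (log2 −0.02, SE 0.20). Its partners METTL14 and WTAP stood at 0.09 (SE 0.16) and 0.06 (SE 0.17), and the erasers FTO and ALKBH5 at 0.24 (SE 0.15) and −0.21 (SE 0.16). The 2 members with an unadjusted p below 0.05 were the reader IGF2BP2, at 14.7 ± 1.49 and 11.1 ± 0.79 CPM (log2 −0.42, SE 0.15), and RBMX (log2 0.40, SE 0.18). The remaining writers and their cofactors were METTL16 at 0.30 (SE 0.20), CBLL1 at 0.23 (SE 0.17), RBM15B at 0.23 (SE 0.20), ZC3H13 at 0.20 (SE 0.20), RBM15 at 0.18 (SE 0.23) and VIRMA at −0.03 (SE 0.20). The remaining measured readers were FMR1 at 0.16 (SE 0.15), YTHDF1 at 0.20 (SE 0.19), YTHDF3 at 0.12 (SE 0.18), YTHDF2 at −0.02 (SE 0.15), HNRNPC at −0.11 (SE 0.17), YTHDC2 at −0.17 (SE 0.21) and HNRNPA2B1 at −0.34 (SE 0.21). For HNRNPA2B1, healthy heart 5 lay at 670 CPM and the other healthy hearts at 320 to 446. The readers YTHDC1, IGF2BP1 and IGF2BP3 of the fixed list were not among the 20 genes measured. With library sizes alone as scaling, which moved the median of all genes from −0.026 to 0.118, METTL3, YTHDF2, VIRMA and HNRNPC lay at 0.10, 0.11, 0.09 and 0.04, on the other side of 0.

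Among the lists that did not pass camera, PDK4, a kinase that turns off glucose oxidation in mitochondria, had a log2 fold change of 1.99 (SE 0.33) and was the 1 fatty acid oxidation gene that passed when adjusted over the list alone (adjusted p = 0.00116 there and 0.0721 over all genes). MYH6, the alpha heavy chain of myosin, stood at −2.94 (SE 0.66, adjusted p = 0.0174 over the list alone and 0.110 over all genes) and was 1 sarcomere gene of 22. NKX2-5, HAND2 and HAND1 were the 3 cardiac transcription factors lower over the list alone, at −0.97 (SE 0.21), −0.95 (SE 0.26) and −0.54 (SE 0.16). The interferon-induced genes XAF1 and IFI44L passed over their list alone at 0.82 (SE 0.20) and 0.73 (SE 0.21), as did the heat shock list's CACYBP at −0.74 (SE 0.16). These members of lists outside the naming rule were chosen after their values were seen.

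The medians and camera adjusted p of these lists were 0.44 and 0.0511 for the sarcomere, −0.17 and 0.198 for calcium handling, −0.21 and 0.773 for fatty acid oxidation, −0.23 and 0.0572 for nuclear genes of oxidative phosphorylation, and −0.32 and 0.0987 for glycolysis. They were −0.05 and 0.983 for MAP kinase and calcineurin-NFAT signalling, −0.09 and 0.0908 for cardiac transcription factors, −0.14 and 0.793 for heat shock proteins, and 0.005 and 0.611 for the interferon response. Among cell-type markers they were 0.34 and 0.172 for atrial, −0.02 and 0.325 for ventricular, 0.06 and 0.365 for endothelial, −0.06 and 0.875 for smooth muscle and pericyte, and 0.42 and 0.0928 for adipocyte markers. They were 0.01 and 0.834 for lymphocyte, −0.87 and 0.0835 for mast cell and neutrophil, 2.35 and 0.0835 for red blood cell (4 genes measured), −0.26 and 0.0835 for nerve and Schwann cell, and −0.01 and 0.669 for mesothelial and epicardial markers. Over their lists alone, GJA1 passed as lower among ion channels and among ventricular markers, NPPA as higher and STARD10 as lower (−1.20, SE 0.35) among atrial markers, SOX17 as higher among endothelial markers, and KRT8 as lower (−0.86, SE 0.24) among mesothelial markers.

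The authors' deposited DESeq2 table called 1013 of 16971 genes, 418 higher and 595 lower. Among its called coding genes tested here, with a mean log2 CPM of at least 1 and no overlap between the groups of hearts, the increases included ABCG2, a transporter of xenobiotics and porphyrins (log2 3.34, SE 0.56), CHRDL1 (2.52, SE 0.36), PI16 (2.15, SE 0.43) and PDK4 (2.01, SE 0.35). The decreases with the same limits included G0S2, an inhibitor of triglyceride lipase (−3.53, SE 0.37), SPP1, which codes for osteopontin (−3.15, SE 0.56), and CD14 (−1.98, SE 0.25). NPPA (3.11, SE 0.81) and MYH6 (−3.255, SE 0.37) were also called there, with groups that overlapped. These genes were chosen after their values were seen. Of its calls 933 were tested here, 933 of which had the same sign and 854 an unadjusted p below 0.05. Across 14950 genes, which are not independent replicates, the log2 fold changes of the table and of edgeR had a Pearson's r of 0.97. Both come from the same input libraries, so that this agreement is expected and gives no separate support.

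The IP raised some transcripts and depleted others alike in both conditions. TMEM186, which codes for an assembly factor of mitochondrial complex I (chromosome 16, 8780384 to 8797648), had a log2 ratio of IP to input of 4.13 (SE 0.31) in healthy and 4.42 (SE 0.31) in failing hearts. NCBP2AS2 had 4.25 (SE 0.23) and 4.24 (SE 0.23), KTI12, a factor of tRNA modification by Elongator, had 4.06 (SE 0.39) and 4.43 (SE 0.40), and SNRNP35, a protein of the minor spliceosome, had 4.18 (SE 0.28) and 4.05 (SE 0.28). OXCT2, an enzyme of ketone use, had 4.54 (SE 0.85) and 3.72 (SE 0.79), and JAML, an adhesion molecule of leukocytes, had 4.2 (SE 0.53) and 3.98 (SE 0.53).

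At the other end, RHOT1, which codes for a GTPase of mitochondrial transport, had −5.19 (SE 0.48) and −5.32 (SE 0.49), and ODC1, the first enzyme of polyamine synthesis, had −5.15 (SE 0.63) and −5.27 (SE 0.62). The calcium-binding protein gene NECAB1 had −5.27 (SE 0.63) and −4.61 (SE 0.60), the mitochondrial ATPase gene ATAD1 −4.83 (SE 0.38) and −5.04 (SE 0.38), RPL10, a protein of the large ribosomal subunit, −4.66 (SE 0.59) and −4.67 (SE 0.59), and ATXN10 −4.66 (SE 0.60) and −4.58 (SE 0.59). All 12 genes passed in both conditions.

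Of 18094 genes, 5377 were higher and 5696 lower in the IP than in the input of healthy hearts, and 5491 and 5722 in failing hearts. In both conditions 4892 genes were higher and 5174 lower, and 0 went opposite ways, where edgeR alone was used and 11769 and 11846 genes had an unadjusted p below 0.05. The log2 ratios of the 2 conditions had a Pearson's r of 0.94 across genes, which are not independent replicates. The IP libraries of healthy hearts 3 and 4 had counts for the fewest genes (14825 and 18849, against 22900 to 26622 in the other 8).

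Ribosomal protein genes had the lowest median ratio of the 29 lists (−2.88 in healthy and −2.91 in failing hearts) with 30 of 31 lower in the IP in each condition. Glycolysis (−1.76 and −1.92), nuclear oxidative phosphorylation (−1.51 and −1.60), fatty acid oxidation (−1.36 and −1.50) and mitochondrially encoded genes (−1.76 and −1.40) also had low medians. Immediate early genes had medians of 1.59 and 1.51, with 11 and 14 of 23 members higher and 0 lower by edgeR, and lymphocyte markers 1.86 and 1.91. TGF-beta genes had medians of 0.97 and 1.14 and macrophage markers of 0.74 and 0.70. The m6A machinery had −0.04 and −0.01, with 9 of 20 members higher and 7 lower in each condition, and among these YTHDF2, an m6A reader that speeds RNA decay, stood at 2.68 (SE 0.20) and 2.77 (SE 0.20) and was chosen after its values were seen. With library sizes alone as scaling, the median of all genes moved from 0.002 to 0.341 in healthy and from 0.025 to 0.209 in failing hearts.

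**Figure D3:**
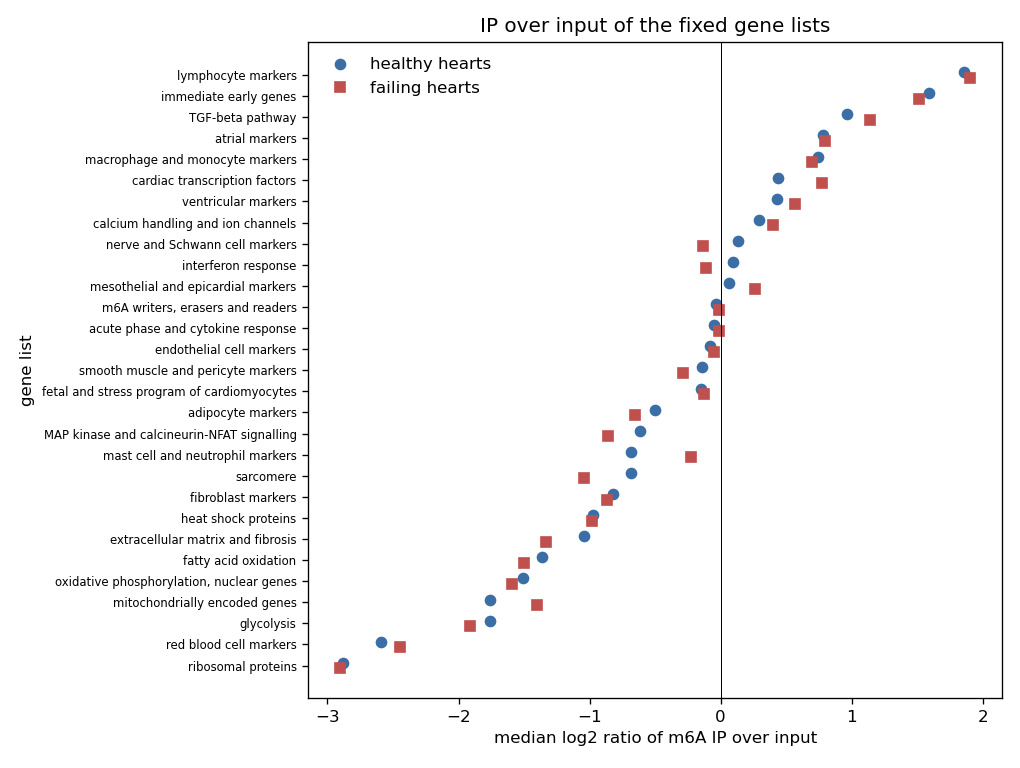
Median log2 ratio of IP to input of each of the 29 gene lists, with circles for healthy and squares for failing hearts. Ribosomal proteins had the lowest medians (−2.88 and −2.91), and lymphocyte markers the highest (1.86 and 1.91).

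No gene passed for a change of IP enrichment between conditions, neither by edgeR (0 of 18094, with 232 at an unadjusted p below 0.05 and 905 expected by chance) nor by DESeq2 (0), nor with the heart as a block (0, with 806 at an unadjusted p below 0.05). Without the block the model ignores that input and IP come from the same heart, so its SE and p are too large. The median SE was 0.534 without and 0.337 with the block. The 232 genes are thus no sign that enrichment is unchanged. Among the 8 genes each way with the smallest p, none of which passed, RNF220, a ubiquitin ligase, had log2 ratios of IP to input of −1.03 ± 0.36 in healthy and −2.03 ± 0.43 in failing hearts (SD, n = 5), a difference of −0.998 (SE 0.27). UNC13D, which codes for a factor of granule release in immune cells, had −0.35 ± 0.33 and −1.82 ± 0.43, a difference of −1.50 (SE 0.43). The fitted differences were 1.83 (SE 0.67) for MT1X, a metallothionein gene, and 0.58 (SE 0.23) for ICE1, a subunit of the little elongation complex. DCT, an enzyme of melanin synthesis, had a fitted difference of 6.79 (SE 1.82), or 3.66 without healthy heart 3, which lay at −8.42, and 4.49 with the heart as a block. Of the other genes, 5 lay between 0.73 and 1.45 (FARS2, ZNF107, TMEM47, PDIK1L, ZNF572) and 5 between −0.99 and −2.78 (SNRPA1, ME1, PPP1R3B, TAX1BP3, PGAP1), and 1 heart carried part of the difference of PPP1R3B (−2.78, or −0.47 without healthy heart 5) and PDIK1L (0.935, or 0.61 without healthy heart 3). Simulated changes of 1 on the log2 scale were recovered in 2.0% and of 2 in 48.0% of genes without the heart as a block, and in 34.0% and 80.0% with it. The shares without the block come from libraries drawn independently of the heart and are not the power in these data.

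Of the 29 lists 0 passed camera for a change of enrichment (lowest adjusted p = 0.515), and 0 passed with an estimated correlation or with fry. The mitochondrially encoded list had a median change of 0.37 with 13 of 13 members above 0. Its adjusted p was 0.01 without failing heart 4 and 0.0236 without failing heart 5. No member of any list passed over all genes.

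The deposited peak lists held 23647 peaks in 12278 genes for healthy and 25640 peaks in 13158 genes for failing hearts, with a median width of 240 bases in each. Of the healthy peaks 86.8% overlapped a failing peak, and of the failing peaks 77.4% overlapped a healthy one. Peaks with the smaller p in each list were shared at 96.8% and 97.4% and those with the larger p at 76.8% and 57.3%. In 11348 genes a peak was listed in both conditions, in 930 in healthy hearts alone and in 1810 in failing hearts alone. The lists have no replicates, so the differences were not tested.

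Of 23647 healthy and 25640 failing peaks, 13791 and 14397 could be placed on the chosen transcripts. The others lay in genes without a coding transcript or partly outside the chosen one, and are not covered here. Placed peaks gathered around stop codons, where m6A is known to be dense. Within 200 bases of the stop codon lay 26.1% of 13791 placed peaks in healthy and 25.1% of 14397 in failing hearts, against 11.2% and 11.3% of random positions in the same transcripts. The 3′ UTR beyond held 26.3% and 26.1% (random 37.9% and 37.4%), the coding sequence 38.2% and 39.8% (random 42.7% and 43.0%) and the 5′ UTR 9.45% and 9.08% (random 8.25% and 8.33%). DRACH motifs occurred 22.7 times per kb of peak in each condition, against 17.7 and 18.0 in matched stretches outside peaks. Exons of at least 400 bases held 92.2% and 91.9% of placed peaks and 73.0% and 73.2% of random positions.

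**Figure D4:**
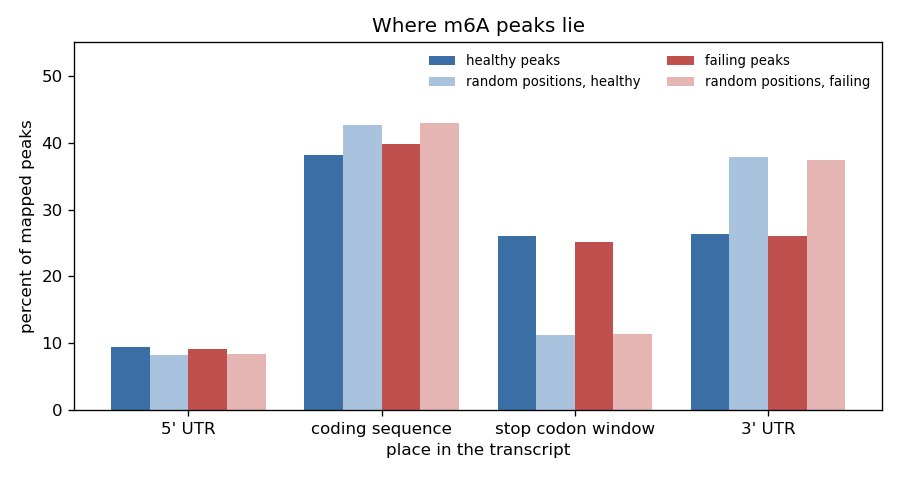
Percent of placed peaks and of random positions in the 5′ UTR, the coding sequence, the window around the stop codon and the 3′ UTR, as bars for healthy and failing hearts. The stop codon window held 26.1% and 25.1% of peaks and 11.2% and 11.3% of random positions.

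The deposited list of differential peaks held 5169 peaks in 3896 genes, with p up to 0.13 and 3299 peaks below 0.05, and gave no direction. Its 5 genes of smallest p were FLNC, the muscle filamin (chromosome 7, 128858795 to 128859244, 3′ UTR), ACTA1, skeletal alpha-actin (chromosome 1, 229433013 to 229434098), TCAP, the titin cap (chromosome 17, 39665349 to 39666464, stop codon window), MALAT1, a nuclear noncoding RNA (chromosome 11, 65500082 to 65500980), and CRYAB, a small heat shock protein (chromosome 11, 111911489 to 111923722). The authors' p, made without stated use of replicates, was 3.3e-189 for the first 3, 1.3e-143 for MALAT1 and 2.6e-142 for CRYAB. At the level of the whole gene their changes of IP enrichment were −0.25 (SE 1.11), −0.30 (SE 1.42), 0.16 (SE 0.42), −0.06 (SE 0.40) and 0.04 (SE 0.64) without the heart as a block. With it they were −0.37, −0.15, 0.11, −0.001 and 0.16. The unadjusted p of the blocked edgeR F test was 0.0775 for FLNC and 0.419 to 0.995 for the others. Of the differential peaks 76.2% overlapped peaks of both condition lists, 10.3% of the failing list alone, 7.33% of the healthy list alone and 6.21% of neither.

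Of the 2 genes called by edgeR for expression, 1 had a differential peak (odds ratio 2.07, 95% interval 0.0263 to 162, Fisher's exact p = 0.546). Among genes called in the authors' expression table, differential peaks were more frequent, with 8.62% of 3526 genes with such a peak called and 5.55% of the other genes with a listed peak (odds ratio 1.61, 95% interval 1.37 to 1.88, Fisher's exact p = 3.51e-09). Abundance, which can raise the power of both calls, was not held equal here. The peaks and the expression table also share input libraries, so that noise common to both can enter this overlap. Genes are not independent replicates in these tests.

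Genes with a peak had higher ratios of IP to input than genes without, at a median of 0.70 against −1.45 in healthy and 0.75 against −1.67 in failing hearts. Per heart the difference was 2.12 ± 0.21 in healthy (SD, n = 5, range 1.93 to 2.41) and 2.29 ± 0.25 in failing hearts. Of genes higher in the IP, 94.3% in healthy and 97.9% in failing hearts had a peak of their condition, against 36.0% and 35.9% of genes lower in the IP. Peaks and ratios come from the same libraries, so that this agreement is expected.

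The expression change and the change of IP enrichment had, when each came from different hearts, a mean Pearson's r across genes of −0.008 (SD 0.013) over 100 divisions of the hearts. When all hearts entered both, so that the same input libraries were used with opposite sign, r was −0.205. Genes are not independent replicates here.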

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

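Of the tests in this part, the counts over other divisions of the samples for the change of IP enrichment were chosen only after that result was seen, and the comparison of IP libraries was added after the data had been seen.

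Healthy heart 2 stood apart from the other 4 healthy hearts in several input values, with XIRP2, a stress-responsive protein of the intercalated disc, at 6403 CPM, the collagen gene COL1A1 at 1007, the matrix gene TNC at 209, the keratin gene KRT8 at 139 and FOSL1 at 23.4. Failing heart 1 held the highest failing values of RBMX (62.7 CPM), YTHDF1 (34.5), YTHDF2 (27.4), MSS51 (22.4), S100A9, a calcium-binding protein of neutrophils (20.5), and CSF3R (6.25), each apart from the other 4. A value counts as apart when its distance to the nearest other heart is above 0.71 of the range of the group.

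Single values lay apart in other hearts as well. In healthy hearts these were the highest values of MT-ND3 (10950.3 CPM in heart 4), NPPA (161 in heart 5), the globin gene HBB (73.1 in heart 1), PLCB1 (8.83 in heart 1) and CD79B (7.86 in heart 4), and the lowest number of genes with a count in an input library (23207). In failing hearts they were the highest values of GPD1 (13.9 in heart 3), FCER1G (6.58 in heart 3) and PRG4 (6.83 in heart 5), and the lowest of STEAP4 (18.9 in heart 4). The log2 ratio of IP to input of SNRPA1 was −0.2 in failing heart 1 and −1.21 to −1.53 in the other 4. Chance marks about 1 in 20 groups in this way, and 22 of 226 groups were marked.

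Macrophage and monocyte markers were lower in failing hearts (median log2 −0.98). The tables argue against gene length and GC content as the whole cause, since the median of random lists matched on length, GC content and expression was −0.15. The list lay at percentile 0.01 of them, the smallest that 10000 lists can give. That percentile is too extreme, as the lists were drawn gene by gene whereas the markers move together (estimated correlation 0.58). The difference between conditions did not shrink with the share of reads outside genes in the model, at −0.90 (SE 0.29) per heart without and −1.12 (SE 0.45) with that share. The share was at most 15.2% in healthy and at least 15.6% in failing input libraries. It thus parts the groups completely, and 10 hearts cannot settle whether it contributes. At the preset correlation 4 of 100 divisions, the real one included, gave a camera p as small as the real 1.26e-12. Other divisions thus reach such a p and the list is 1 of 29 tested, so chance is not excluded. The smallest camera p of the others was 7.66e-19. The preset correlation of 0.01 lies far below the estimated 0.58 of these markers, so such p can arise without any further structure of the samples. The list did not pass with an estimated correlation (adjusted p = 0.554) or with directional fry (0.156). A smaller number of macrophages in failing tissue stays open, as 13 of 16 markers lay within 2 SE of the list's median, and so does a lower expression per cell, which was not tested.

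Ribosomal protein genes and mitochondrially encoded genes were lower in failing input libraries, which also held more reads outside genes (17.8% against 13.3%), a signal in reads that the comparisons of genes do not use. The median of the ribosomal list, −0.41, lay at percentile 0.97 of lists matched on gene length, GC content and expression (median −0.26). Those lists were drawn gene by gene, whereas ribosomal protein genes move together (estimated correlation 0.66). The spread of the matched lists is therefore too narrow, and this test cannot exclude gene length and GC content. With the share of reads outside genes in the model the difference per heart went from −0.38 (SE 0.19) to −0.07 (SE 0.26) for ribosomal and from −0.63 (SE 0.20) to −0.56 (SE 0.31) for mitochondrially encoded genes, so that the share and the condition cannot be told apart with 10 hearts. Chance cannot be excluded for either list, with a real camera p of 4.76e-07 and 6.35e-08 and the smallest p of the other divisions at 5.45e-20 and 1.98e-11 (20 and 9 of 100 divisions gave a p as small). A difference in RNA quality or nuclear RNA content may underlie both the share and the lists as well as heart failure itself, since −0.07 and −0.56 decide neither.

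For the counts of genes, divisions of the 10 hearts or libraries into 5 and 5 were compared, of which 100 were drawn. With the expression calls of edgeR, 1 of 100 divisions gave as many, the real one with 2 genes, and the highest of the others gave 1. That count is too small to exclude chance, as it fell to 0 in some fits with 1 heart left out. For the expression calls of DESeq2 the real division also gave the most (1 of 100, 568 genes against at most 269). This is under 0.05, but not corrected for the other counts examined in this way. Chance is thus unlikely for that count and not excluded. For IP against input, 1 of 100 divisions gave as many in healthy hearts (the real one, 11073 genes against at most 2802) and in failing hearts (11213 against at most 686). Most of these divisions break the pairing of input and IP library by heart. Only 9 of those drawn, the real one included, part the 2 libraries of every heart, with 1662 and 0 as the highest other counts. The real count was the largest of the 9 in each condition, but 9 divisions are too few to exclude chance at 0.05 whatever the data. The 2 conditions come from different hearts, and their ratios had a Pearson's r of 0.94 across genes. In both conditions 4892 genes passed as higher and 5174 as lower, and 0 went opposite ways. These values argue against chance as the source of the IP against input counts. Chance cannot be excluded for the number of gene lists past the threshold for expression (44 of 100, 9 lists against at most 15) or for the comparison of IP libraries (5 of 100, 56 genes against at most 604). For the change of IP enrichment the real counts were 0 genes by edgeR, with 232 at an unadjusted p below 0.05 and 0 by DESeq2, and 0 lists, which any division reaches (100 of 100, at most 1 gene and 6 lists in the others), so that these counts decide nothing about chance. The 604 genes of another division of the IP libraries point to a structure of the samples other than the condition. That division set healthy hearts 1, 2 and 5 and failing hearts 1 and 2 against the rest. In the IP libraries of hearts 1 and 2 of both conditions, 10.1% to 14.4% of the genes with a count had 1 count. In the other IP libraries this share was 2.48% to 7.19%. What sets these hearts apart was not tested.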

How the results depend on the processing

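The settings without healthy hearts 3 and 4, without healthy heart 2 and failing heart 1, and the comparison of IP libraries were chosen after seeing the data, and no measured rule stood behind the pair of healthy heart 2 and failing heart 1. The number of expression calls, 2 in the reported fit, was 9 with library sizes alone (8 higher, 1 lower), 488 without a filter on low counts, 568 with DESeq2, 1 with all 20 libraries in the fit (CHRDL1 no longer passed), 67 without healthy hearts 3 and 4, 6 without healthy heart 2 and failing heart 1, and 0 with the replicate number as a block across conditions, by edgeR where no tool is named. With 1 heart left out it ranged from 0 (without failing heart 2, 4 or 5) to 133 (without healthy heart 3), with 5 without healthy heart 2 or 5 and 4 without failing heart 3. DESeq2 size factors and non-robust fits kept it within 1.5 times. The block pairs different hearts by their number. In hearts 1 and 2 of both conditions, 17.4% to 17.9% of the genes with a count in the input had 1 count. In the other hearts this share was 12.7% to 15.7%. The number may thus carry a factor that both conditions share, which was not tested. The cause of the changed counts was not tested for any of these settings.

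The 9 gene lists past camera for expression became 0 with an estimated correlation and 0 with fry, which does not compare a list with other genes, and 5 to 13 with 1 heart left out (5 without failing heart 4). With library sizes alone 7 lists passed (2 up, 5 down), among them sarcomere genes (0.0467) and mast cell and neutrophil markers (0.0263), which had not passed before. The fetal, matrix, TGF-beta and fibroblast lists then had adjusted p of 0.0845, 0.103, 0.0656 and 0.0805. The matrix list changed direction without healthy hearts 3 and 4, at an adjusted p of 0.975 (over the fits with 1 heart left out 3.81e-10 to 0.367). For the change of IP enrichment 0 lists became 1 without failing heart 4 or 5 and stayed 0 in the other fits with a heart left out.

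Counts of IP against input stayed within 1.5 times in all settings, with library sizes alone splitting them as 6536 and 4724 in healthy and 6117 and 5241 in failing hearts. That scaling moved the median of all genes for expression from −0.026 to 0.118 and for the change of enrichment from 0.024 to −0.132, and DESeq2 size factors moved IP against input in failing hearts from 0.025 to −0.088. The 0 genes with a change of enrichment stayed 0 in every setting run, by edgeR and DESeq2, with 232 at an unadjusted p below 0.05 in the reported fit. With the heart as a block, the test recovered 80.0% of simulated changes of 2 on the log2 scale. Without the block it recovered 48.0%, on libraries drawn independently of the heart, unlike the real ones. The 56 genes of the IP libraries became 4 (without failing heart 5) to 578 (without healthy heart 3) with 1 heart left out, with 101 without healthy heart 2, 11 without failing heart 2 and 14 without failing heart 3 or 4, and 774 without healthy hearts 3 and 4.

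Shared peaks were 85.8% and 76.4% when 50% of the shorter peak had to overlap, 91.1% and 82.9% for the part of each list with the smaller p, and 92.4% and 86.2% by gene. The gap between genes with and without a peak in healthy hearts went from 2.15 to 2.44 among genes with a mean log2 CPM of at least 1. The odds ratio of differential peaks, 2.07 from 2 called genes (0.0263 to 162), was 4.75 for the part of the differential list with the smaller p (Fisher's exact p = 0.317). It was 1.61 with the authors' table and then passed Fisher's exact test, as more genes are called there. The correlation of −0.008 between both changes became −0.205 with all hearts, where shared input libraries enter with opposite sign. Of the named genes' values under other settings, 10 lost and 35 gained a call for expression, and the other 1747 for expression, 432 for IP over input and 320 for the change of enrichment stayed on their side of the threshold, which says nothing of the sign of values that did not pass.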

Other observations

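The comparison of failing with healthy IP libraries and the tests of differential peaks against blocked fits, and the genes named here, were chosen after the data had been seen, whereas the bounds for the tests of exon length were written before those tests were run.

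Among the IP libraries alone, 56 genes differed between failing and healthy hearts by edgeR, 27 higher and 29 lower. CD14 had a log2 fold change of −2.12 (SE 0.28) there and −1.87 (SE 0.23) in the input, PDK4 had 2.45 (SE 0.38) and 1.99 (SE 0.33), and G0S2 had −3.31 (SE 0.59) and −3.25 (SE 0.56). ANTXR1, a collagen-binding receptor, had 1.33 (SE 0.22) and 1.03 (SE 0.17), and the proliferation marker MKI67 had −3.18 (SE 0.61) and −3.18 (SE 0.61). Of 52 of these genes measured in the input fit, 51 had the same sign there and 45 an unadjusted p below 0.05, with a median size of 1.38 in the IP and 0.81 in the input. The IP and input libraries come from the same hearts, so that a shared sign is expected for any division of the hearts. RNF220 had −1.32 (SE 0.19) in the IP and −0.33 (SE 0.14) in the input. The count was 578 without healthy heart 3, 101 without healthy heart 2, 11 without failing heart 2, 14 without failing heart 3 or 4 and 4 without failing heart 5.

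In the IP libraries camera passed 6 lists, namely macrophage and monocyte markers (median −0.94, adjusted p = 1.94e-08), immediate early genes (0.70, adjusted p = 0.000696), ribosomal proteins (−0.35, adjusted p = 0.000696), acute phase and cytokine genes (−0.27, adjusted p = 0.0194), nuclear genes of oxidative phosphorylation (−0.22, adjusted p = 0.0194) and mitochondrially encoded genes (−0.36, adjusted p = 0.0305). With an estimated correlation the adjusted p of these lists was 0.831.

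Genes with 1 exon in their chosen transcript had a median log2 ratio of IP to input of 1.94 in healthy and 1.97 in failing hearts (364 genes), those with 2 to 3 exons 1.33 and 1.43 (1521 genes), those with 4 to 10 exons 0.04 and 0.07 (5985 genes), and those with 11 or more −0.67 and −0.72 (5639 genes). Of 13509 coding genes put into 3 equal parts by their longest exon, the top part lay 0.96 above the bottom part. Within 10 bins of transcript length the difference was 1.34 on average (0.44 to 1.86), within 10 bins of GC content 1.24 (0.43 to 2.03) and within 10 bins of abundance in the input 0.96 (0.67 to 1.16), positive in 10 of 10 bins each. These values argue against transcript length, GC content or abundance as the whole cause. A candidate explanation is that m6A is laid down mainly in long exons, and a bias of the IP or of fragmentation towards such exons stays open.

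Differential peaks lay in genes with an unadjusted p below 0.05 for the change of IP enrichment more often than elsewhere when the heart was a block, in 11.2% of 3626 genes with such a peak and 2.71% of the others (odds ratio 4.52, 95% interval 3.83 to 5.35, Fisher's exact p = 2.35e-75). Without the block these shares were 1.21% and 0.52% (odds ratio 2.35, 1.52 to 3.63). Within 10 bins of abundance the odds ratio with the block was 4.28 (3.54 to 5.17). In that blocked fit 0 genes passed, 806 had an unadjusted p below 0.05 and 905 would be expected by chance, and the peaks and the counts come from the same libraries, so that noise shared by both enters the overlap.

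On a plot of distances between libraries of 1 kind, the IP library of healthy heart 3 lay at −4.39 on the leading axis while the other 9 lay between −0.04 and 0.77.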
